A study of Drosophila melanogaster with 2 samples.

How the data were processed

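Chromatin immunoprecipitation followed by sequencing was done on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. The flies carried a transgene that fuses ventral veins lacking (vvl), a POU-domain transcription factor, to eGFP, and the precipitation used an antibody against GFP. Chromatin was sonicated to 200 to 800 bp, per the labels. There were 2 samples in 1 group, labelled as biological replicates 1 and 2 from separate biosamples. The labels name a possible control experiment, which was not used here.

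The deposited files are 8 peak lists in dm6 coordinates, of which 4 are thresholded and 4 ranked. According to the text files that accompany them, the lists of the whole series were derived from the alignments of both replicates and each replicate's lists from its own alignments, together with 1 further file common to all lists. The aligner, the peak caller and their versions are not given in the sources used here. In each list the authors gave every peak a signal, a score of at most 1000 and a summit position. The deposited ranked lists also hold the −log10 of the irreproducible discovery rate (IDR), a measure of how well a peak's rank is kept between 2 rankings. The lowest score in all 4 deposited thresholded lists was 830, and each of these lists holds only ranked peaks with a −log10 IDR of 2 or more, an IDR of 0.01 or less. Peak signal is the authors' own value per peak and was used only to rank and describe peaks. Because peak lists carry no read counts, the depth of each sample is unknown.

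The conservative list of the series, with 8309 peaks, was the main peak set. The broader list of the series held 11692 peaks, replicate 1 alone 9050 and replicate 2 alone 7098. Of the 8493 ranked peaks at or under the IDR threshold in the matching ranked list, 184 are not among the 8309 and were not analysed here. They lay mainly on 3R, with 115 of the 184, and densities on that arm and counts of genes with a peak leave them out. Why they are absent from the thresholded list is not known. Work on coordinates was limited to the 6 arms 2L, 2R, 3L, 3R, 4 and X, apart from peak density, which includes Y. The sequence was the Release 6 assembly of the genome. Genes and transcripts came from Ensembl release 115, without transposable elements.

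Replicates were compared by the share of peaks overlapping by 1 bp or more, against 1000 shuffles of the peaks within their arm (1-sided permutation test). Summits were assigned to 1 location class in the order promoter (within 500 bp of a transcription start site, TSS), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and compared with 1000 uniform placements in the same arms (2-sided permutation test). The smallest p that 1000 draws can give is 0.001 for the 1-sided and 0.002 for the 2-sided test. Words were sought on both strands within 100 bp of summits and in windows centred 1000 bp to each side that held no peak, with Fisher's exact test and Benjamini-Hochberg adjustment over 18 fixed words, 2 of them composition controls. All 2080 strand-merged 6-mers were tested in the same windows, with adjusted p under 0.05 and an odds ratio over 1.5 or under its inverse. Intervals are at 95% and, for shares, Wilson or exact binomial. Intervals of odds ratios and of differences use the normal approximation. They cover counting error over peaks, which are not replicates. Location classes were adjusted over the 7 classes of a list, by Benjamini-Hochberg.

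For 20 fixed gene lists, protein-coding genes with a summit in the gene body or within 2000 bp were counted and compared with 10000 random lists matched in 20 bins of gene-window length (2-sided permutation test, smallest p 0.0002), with Benjamini-Hochberg adjustment over the lists. The background was 13945 protein-coding genes. Another 5 symbols of the lists were not used here. The text names vvl and the other POU genes, the genes with the TSS nearest to the 20 highest-signal peaks, the 10 genes with the most summits, and up to 4 genes per list by the signal of their best peak. Genes whose TSS lay nearest to such a peak are named too where they differ, chosen after the values were seen. A gene that this rule takes is not reported here. The main tests, the lists, the words, this rule and all alternatives but 1 were fixed before the data were examined. Added afterwards were the alternative that leaves out genes near the passing peaks not analysed here, all tests of explanations (tRNA genes and their clusters, the octamer at promoters, GC content in coding exons, strong against weak peaks at and away from promoters), the comparison of strong with weak peaks for words other than the octamer, the ratio of X to the other arms, the promoter share by signal, the octamer's position, word tests by signal and by location, the 60 kb around vvl and the adjustment over location classes. Signals of a peak in each replicate were taken from the nearest summit within 100 bp in that replicate's ranked list.

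Alternatives were the broader list, the 4154 highest-signal peaks, each replicate's list alone, other overlap rules, promoter widths and TSS sets, a 50 bp word window, random windows matched in arm, GC content (bins of 2.5 percentage points) and promoter status, peaks away from TSSs only, other gene windows, unmatched random lists, a 2 kb window at vvl and gene lists without genes near the passing peaks not analysed here. The matched random windows had no peak of the broader list within 500 bp of their centre. The word, 6-mer, location, overlap and gene-list steps were tested on simulated data. The comparison of strong with weak peaks and the matching of random windows were not. With no word planted, 0 of 18 words and 0 of 2080 6-mers were called. The simulated summits were placed uniformly, so this does not test differences in location or composition between real summits and their flanks. All 20 simulated lists with raised counts were called, and 1% of 200 unchanged lists of long genes had a permutation p under 0.05 with length matching, against 12% without it. The 12 conservative peaks that repeat an interval with another summit were kept as separate summits. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.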

Results

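Binding of vvl-eGFP was mapped in 2 biological replicates of whole embryos aged 0 to 24 h. vvl encodes a POU-domain transcription factor known for its roles in the trachea, the midline glia, neurons and the wing veins. The conservative list of the series held 8309 peaks with a median width of 396 bp, covering 2689 kb. Peak signal, the authors' value per peak, had a median of 141.3 and reached 3297. With 1 group and no control sample used here, the design gives a comparison between replicates and comparisons of peaks with the genome.

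The highest-signal peaks were mostly at gene starts and were found in both replicates. The first lay at X:2703688-2704074 in the promoter of Ugalt, with its summit 36 bp from the TSS, and ranked 2 in each replicate's ranked list. The next was in an intron of CG11050 at 2L:6612411-6612982. It was followed by promoter peaks of CG14100 (3L:19590435-19590785) and mRpL41 (2R:15217568-15217944). Further peaks among the first 20 were nearest to CG7601, CG18549, CenG1A, Tcs5, PNPase, px, Art3, CG13323, CG5611, CG9147, Fkbp14, Chro and CG8320. The Polycomb group genes ph-p (X:2137172-2137551, rank 10) and Psc (2R:12985016-12985392, rank 18, 4203 bp from the nearest Psc TSS) and the POU gene nub (rank 12) were also in this set. Of the first 20 peaks, 17 were at promoters and 1, at CG11050, carried the octamer. All of the 100 highest-signal peaks overlapped a peak in each replicate's list. Of all conservative peaks, 81.5% overlapped a peak in the list of replicate 1 and 73.4% one in that of replicate 2.

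Replicate 2 shared 5136 of its 7093 peaks on the 6 arms with replicate 1, or 72.4% (95% interval 71.4 to 73.4). In the other direction, 5347 of 9050 peaks of replicate 1 were shared, or 59.1% (58.1 to 60.1). Shuffled peaks of replicate 2 overlapped replicate 1 in 3.92% of cases on average, and never in more than 4.75% (permutation test, 1-sided p = 0.001, the smallest possible). Shuffled peaks of replicate 1 overlapped in 3.16% (permutation p = 0.001). The shuffles did not keep the share of summits at promoters, 43.3% in the list of replicate 1 and 48.2% in that of replicate 2. Part of the excess over them can therefore come from this shared location alone. Across 7297 conservative peaks with a summit in both ranked lists, the rank correlation of the replicates' signals was 0.625. That correlation is across peaks, which are not independent replicates, and these peaks were selected for being found in both.

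Promoters held 45.9% of the summits, 3.37 times the 13.6% ± 0.378 (SD over 1000 placements) of random positions. Introns held 36.2% against 39.3%, and intergenic sequence 14.9% against 27.5%. Coding exons held only 26 summits, 0.313% against 13.0% of random positions. The 3' UTRs held 1.07% against 4.99%. Each of these 5 differences had a 2-sided permutation p of 0.002, the smallest possible (adjusted p = 0.0028). For 5' UTRs the share was 0.578% against 0.771% (permutation p = 0.044, adjusted p = 0.0513), and for other exons 0.963% against 0.814% (permutation p = 0.154). In the broader list the call for introns was lost (permutation p = 0.076) and that for other exons gained (permutation p = 0.024). Other exons also passed in the list of replicate 1 (permutation p = 0.008), and 5' UTRs passed after adjustment in that of replicate 2 (permutation p = 0.002) and in the 4154 highest-signal peaks (permutation p = 0.036, adjusted p = 0.042). They did not pass in the broader list (permutation p = 0.537) or in that of replicate 1 (permutation p = 0.667). The promoter share was 50.6% among the 2077 highest-signal peaks and 43.3% among the 2078 lowest.

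**Figure D1:**
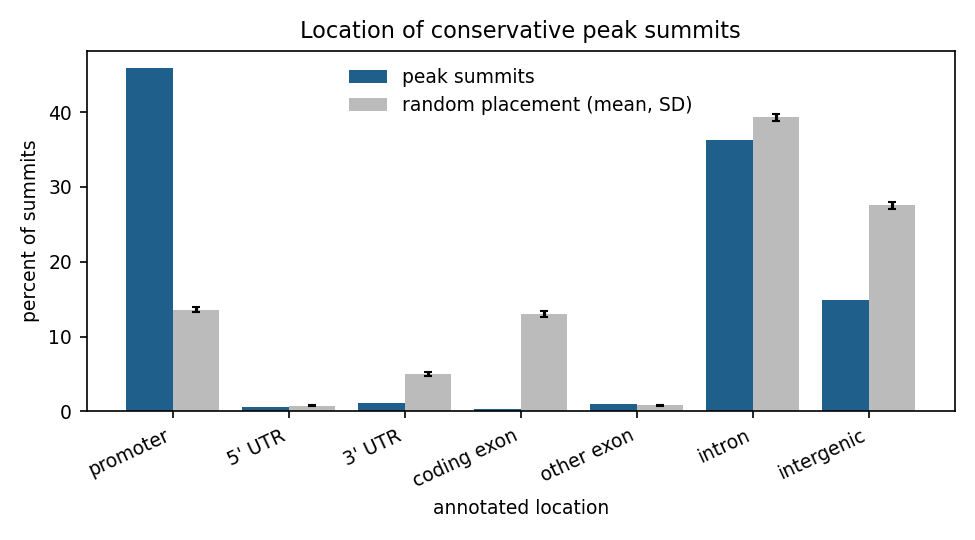
Percent of the 8309 conservative summits (blue bars) and of uniformly placed points (grey bars, mean and SD over 1000 placements) in each annotated location. Promoters hold 45.9% of summits against 13.6% of placed points, and coding exons 0.313% against 13.0%.

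Peaks were spread over the major arms at similar densities. Arm 3L had the highest density, with 67.7 peaks per Mb, followed by 2L with 64.4, 2R with 63.3, 3R with 59.7 and X with 57.9. Chromosome 4, which is small and rich in heterochromatin, had 13 peaks, or 9.64 per Mb, which is 0.156% of peaks (exact interval 0.0833 to 0.267). No peak was on Y (0%, exact upper limit 0.0444%). The density on X was 0.910 times that on the arms of chromosomes 2 and 3 (95% interval 0.859 to 0.965). It was 0.978 times in the list of replicate 2 and 0.814 times in that of replicate 1, so the value depended on the replicate. Sex was not collected, per the labels, and copy number of X differs between sexes. A further 115 passing peaks on 3R were not analysed here.

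The octamer ATGCAAAT, the site that POU-domain proteins are known to bind, was more frequent at summits than beside them. It lay within 100 bp of 555 summits (6.68%) and in 492 of 14991 flanking windows (3.28%), an odds ratio of 2.11 (1.86 to 2.39; Fisher's exact test, adjusted p = 6.70e-31). Other POU words were also more frequent. ATGCTAAT had an odds ratio of 2.13 (exact test, adjusted p = 2.28e-13) and the palindrome ATGCATAT 1.78 (exact test, adjusted p = 9.48e-09). TGCAAAT had 1.35 (exact test, adjusted p = 5.68e-10), but every octamer holds this word. It lay near 867 summits and in 1191 flanking windows, counts that include the 555 and 492 with the octamer. Its ratio is therefore not separate from that of the octamer, and TGCAAAT outside the octamer was not tested. The reversed word TAAACGTA (1.18; exact test, adjusted p = 0.394) and the shuffled word AACATGTA (1.23; exact test, adjusted p = 0.204) did not pass. Among the 2077 highest-signal peaks alone, AACATGTA did pass, with an odds ratio of 2.10, beside 2.14 for the octamer (exact test, adjusted p = 0.0162 and 4.22e-08 over 72 tests). Octamer occurrences were 0.416 and 0.505 per kb in the 50 bp on either side of the summit, and 0.137 to 0.279 per kb in the other bins within 500 bp. The shuffled word AACATGTA, which is rarer, was also higher beside the summit, at 0.0698 and 0.0554 per kb against 0.0193 to 0.0409 per kb.

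The words of 2 promoter factors had larger odds ratios than the octamer. TATCGATA, the DNA replication-related element (DRE), was near 3.80% of summits and in 0.420% of flanks (odds ratio 9.37; exact test, adjusted p = 1.47e-81). GGTCACAC, the site of the promoter factor M1BP, had an odds ratio of 6.74 (exact test, adjusted p = 8.00e-55) and the GAGA word GAGAGAG 2.02 (exact test, adjusted p = 2.07e-25). The homeodomain word TAATTA had 1.34 (exact test, adjusted p = 6.45e-13), the TATA word TATAAAAG 1.60 (exact test, adjusted p = 3.96e-05) and the Twist E-box CATATG 1.13 (exact test, adjusted p = 0.0316). Lower than in flanks were the Zelda word CAGGTAG (0.573; exact test, adjusted p = 1.65e-04), the Sox word ACAATG (0.839; exact test, adjusted p = 8.85e-05) and the GATA word AGATAAG (0.817; exact test, adjusted p = 0.0316). The words TACGTG (bound by bHLH-PAS factors), CAGCTG and AACCGGTT (bound by Grainyhead) did not pass. Against random windows matched in GC content and promoter status, M1BP had 4.76 (3.54 to 6.4) and DRE 4.02 (3.14 to 5.14). GAGAGAG had 3.20 (2.67 to 3.83) and the octamer 2.49 (2.13 to 2.91). The order of these words differed from that against flanks, but neighbouring intervals overlap and differences between words were not tested. Against the matched windows the TATA word turned to 0.903 and did not pass (exact test, adjusted p = 0.402). The Zelda and GATA words no longer passed, and CAGCTG and AACCGGTT did.

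**Figure D2:**
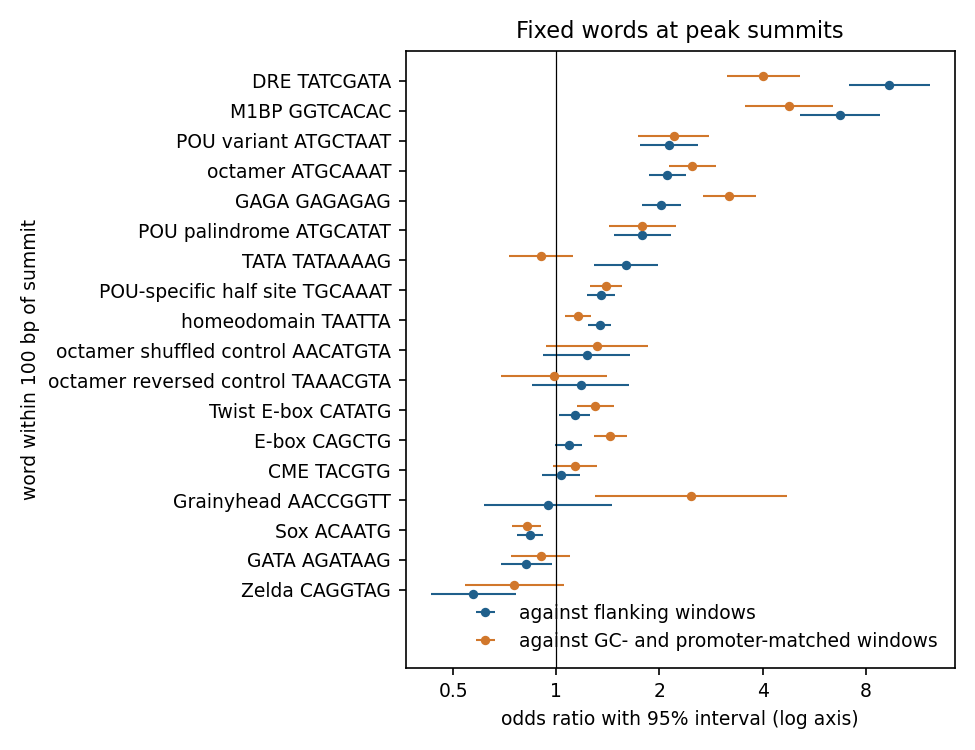
Odds ratios (log axis, 95% intervals) of 18 fixed words within 100 bp of the 8309 conservative summits, against flanking windows (blue) and against random windows matched in GC content and promoter status (orange). DRE and M1BP words lie highest, the octamer lies at 2.11 and 2.49, and both intervals of each control word include 1.

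**Figure D3:**
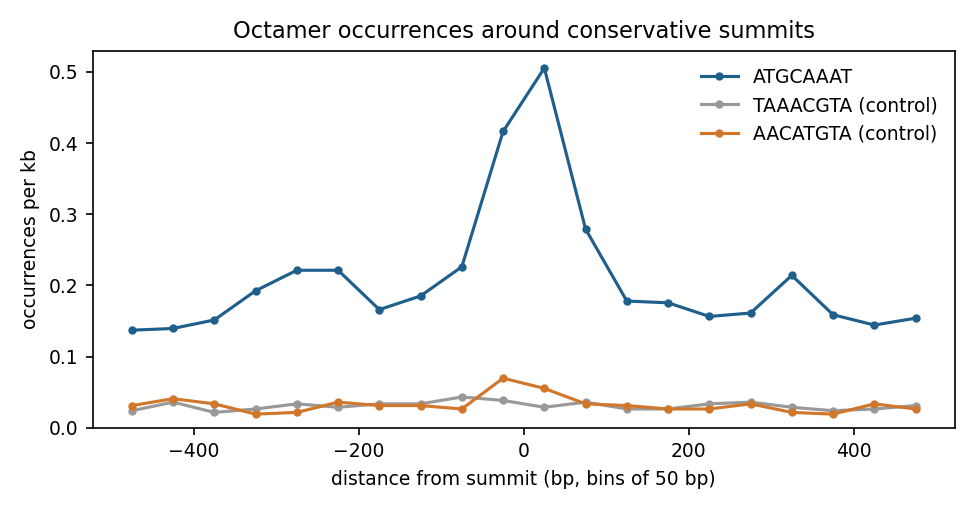
Occurrences per kb of the octamer and of 2 control words in 50 bp bins up to 500 bp from the conservative summits. The octamer is highest in the bin just after the summit, at 0.505 per kb, and the shuffled control AACATGTA in the bin just before it, at 0.0698 per kb.

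Among all 6-mers, 75 were more frequent at summits and 223 less frequent. ACACTG led with 17.5% of summits and 6.87% of flanks (odds ratio 2.88; Fisher's exact test, adjusted p = 2.44e-130). CGATAG followed with 2.535 (exact test, adjusted p = 2.54e-62) and ACAGTG with 2.37 (exact test, adjusted p = 3.08e-88). The lowest odds ratio was that of CCAGGA, with 2.24% against 8.325% (odds ratio 0.253; exact test, adjusted p = 4.96e-86). The octamer's own 6-mers did not reach an odds ratio of 1.5, and the highest was ATGCAA with 1.30. Matched random windows gave 74 more and 102 less frequent 6-mers, and 25 were more frequent in both comparisons. Neither set of windows was matched to the summits in coding exons, where summits were rare. The part of this difference in location in the less frequent words was not tested.

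The octamer share of the highest-signal peaks was not shown to differ from that of the lowest. It was near 132 of the 2077 highest-signal summits (6.36%) and 110 of the 2077 lowest (5.30%), a difference of 1.06 percentage points (-0.365 to 2.48; Fisher's exact test, p = 0.164, adjusted p = 0.306 over 18 words). Against their own flanks, the octamer's odds ratio was 2.14, 2.84, 2.16 and, in the 2078 lowest-signal peaks, 1.46 (1.13 to 1.88), from the highest to the lowest of 4 parts by signal; differences between these parts were not tested. In the list of replicate 1 the difference was 2.21 points (exact test, p = 0.00748), and in that of replicate 2 it was -1.47 points (exact test, p = 0.0581). Within the 4154 highest-signal peaks it was -2.70 points (exact test, p = 0.0171), so the direction depended on the peaks compared. The homeodomain word TAATTA was more frequent in the highest-signal peaks, with 18.5% against 13.0% (exact test, adjusted p = 2.62e-05).

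The vvl locus itself held many peaks. The gene (FBgn0086680, 3L:6790158-6794941) had 9 conservative summits within 10 kb, all outside the gene body, at signal ranks from 279 to 6714. Of 696 protein-coding genes of similar window length, 5 had as many (0.718%), and the median of that length class was 2. The strongest of the 9 was intergenic at 3L:6787467-6787889, 2.46 kb upstream, and 1 lay at the vvl promoter (3L:6789948-6790228). The promoter peak had no summit within 100 bp in the ranked list of replicate 2. The octamer was near 2 of the 9 summits. Within 60 kb there were 44 summits, of which the strongest, at 3L:6853657-6854092, ranked 142. The labels do not say whether the transgene adds a copy of vvl or tags the gene in place. Any added copy would map to this locus, so these counts are not treated as independent of the transgene. Within 2 kb the count was 1.

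**Figure D4:**
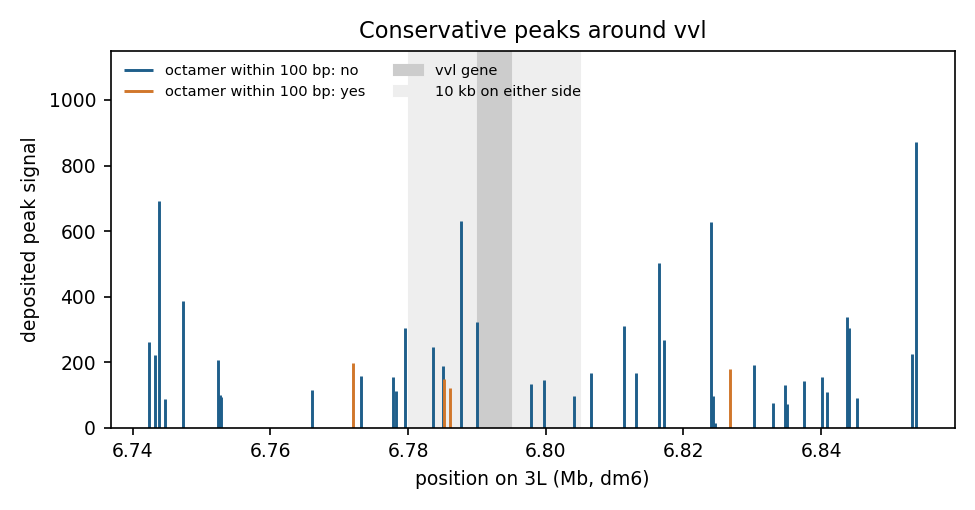
Conservative peaks within 60 kb of vvl on 3L (dm6). Each line is a summit and its height is the deposited peak signal, orange where the octamer lies within 100 bp; dark grey marks the gene and light grey 10 kb on either side, which together hold 9 of the 44 summits.

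Of the POU genes, nub had the strongest peak, at 2L:12586876-12587255, 555 bp from its TSS, with a signal of 2249.5. pdm2 had 3 summits, pdm3 had 2 and acj6 had 0. The POU list as a whole had 4 of 5 genes with a peak, against 3.38 in random lists (permutation p = 0.958, adjusted p = 0.992).

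Tracheal genes carried peaks more often than genes of their length. Of 23, 22 had a summit, against 14.9 in matched random lists (permutation test, p = 0.0026, adjusted p = 0.0173). Their strongest peaks were at salm (2L:11446086-11446364, rank 616), rib (2R:19272193-19272436, rank 758), pnt (3R:23309756-23309990, rank 846) and kni (3L:20692629-20692841, rank 941). pnt, an ETS factor downstream of receptor tyrosine kinases, had 16 summits, and its strongest carried the octamer. This call was lost under 5 of 8 alternatives, where the adjusted p of the permutation test was 0.0853 for the broader list, 0.159 for replicate 2 alone, 0.102 with 10 kb on either side of the gene, 0.746 for summits within 1000 bp of a TSS and 0.856 for the 4154 highest-signal peaks. In the other 3 the call was kept. The adjusted p of the permutation test was 0.0147 for replicate 1 alone. It was 0.0093 without genes near the passing peaks not analysed here, a setting that left out 0 of the 23 genes. With random lists not matched on length it was 0.0013, but that setting does not correct for gene length.

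Ribosomal protein genes had the highest ratio to random lists of the 20 lists, 2.20. A summit was found at 74 of 88, against 33.65 in random lists (permutation p = 0.0002, the smallest possible, adjusted p = 0.002). Examples were RpL3 (3R:11226504-11226810, rank 82), RpL7 (rank 189) and RpS27 (rank 224). The strongest peak of RpL3 had its nearest TSS in the neighbouring gene CG17726. Chemosensory receptor genes, which act in sensory neurons, had peaks less often than random lists. Only 23 of 179 had a summit, against 78.8 (permutation p = 0.0002, adjusted p = 0.002). The strongest of these, near Or85f, Ir68b, Or88a and Ir76b, lay at the TSSs of the neighbouring genes RpL34b, yps, CG12402 and CG14187.

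The other 16 lists and the POU list did not pass. In the EGF and FGF list, 14 of 15 genes had a summit against 10.1 (permutation p = 0.042, adjusted p = 0.21). In the list of replicate 1 all 15 had one and the list passed (permutation test, adjusted p = 0.025), while in that of replicate 2 it was 11 (adjusted p = 0.970 in the permutation test). Its strongest peaks were at aos (3L:16480422-16480713, rank 150, with the octamer), ths, pnt and spi. Wing vein genes had peaks at 12 of 13, against 8.88 (permutation test, adjusted p = 0.361), led by salm, sog, dpp and bs. Among midline and glial genes 15 of 19 had a summit against 12.03 (permutation test, adjusted p = 0.432), with the strongest at moody (rank 105), aos, NetA and sli, which had 9. Notch pathway genes had 9 of 14 against 6.10 (permutation test, adjusted p = 0.427), with peaks at E(spl)m8-HLH, N, numb and E(spl)mdelta-HLH. Hox and segmentation genes had 13 of 20 against 11.98 (permutation test, adjusted p = 0.914), led by Abd-B, Antp, Ubx and wg.

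Another 11 lists did not pass either. Neuroblast genes had 7 of 19 against 10.4, led by nub, grh, pdm2 and Dr, and neuronal genes 9 of 15 against 10.1, led by elav, with ChAT and VAChT sharing a peak, and fne. Epidermal genes had 9 of 16 against 10.3 (grh, Alas, kkv, nyo), and Cpr cuticle protein genes 23 of 70 against 26.8 (Cpr76Ba, Cpr31A, Cpr35B, Cpr65Au). Muscle genes had 9 of 18 against 11.4 (Mef2, kirre, sls, Mlc2), hemocyte and fat body genes 6 of 17 against 9.74 (Lsp2, ush, Col4a1, srp) and gut genes 6 of 13 against 7.04 (Pdp1, mid, bin, fkh). Germline genes had 6 of 11 against 6.47 (bgcn, piwi, ovo, gcl) and heat shock genes 8 of 15 against 6.43 (Hsp23 and Hsp27 at 1 shared peak, Hsp83, Hsp26). Ecdysteroid synthesis genes had 3 of 10 against 5.46 (mld, shd, ouib) and antimicrobial peptide genes 2 of 14 against 3.21 (Def, CecA1). The adjusted p in the permutation test lay between 0.361 and 0.992 for these 11 lists. Of the 71 genes that the rule for named genes takes from the lists, 29 had their strongest peak nearest to the TSS of another gene, such as gro for E(spl)m8-HLH, Pal1 for Mef2, magu for Def and RpS7 for CecA1.

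**Figure D5:**
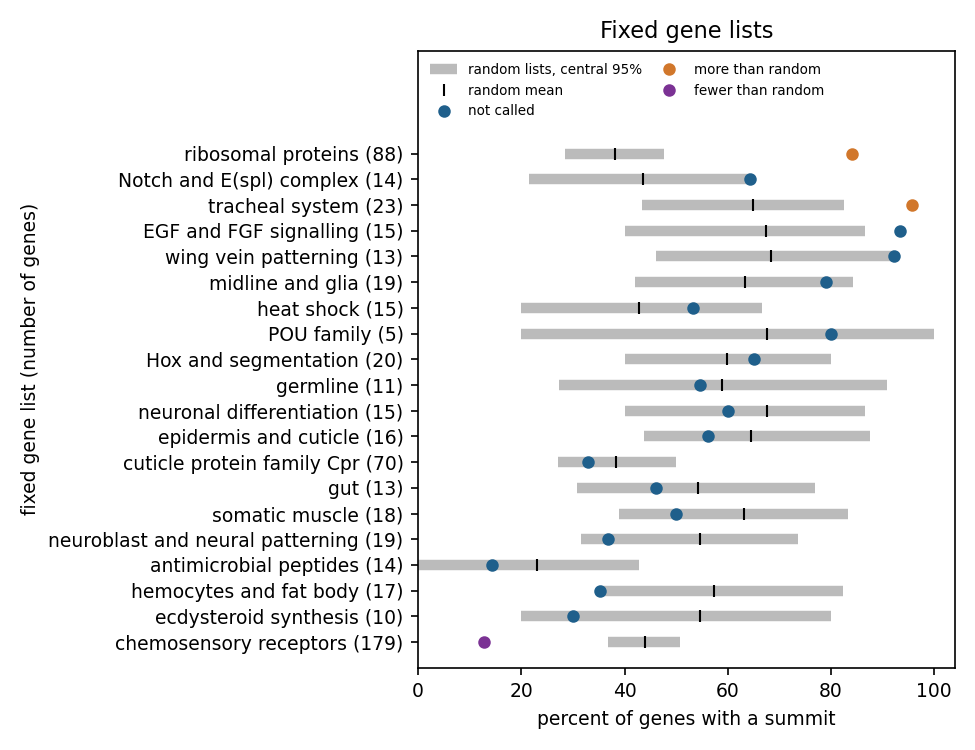
Percent of genes in each of 20 fixed lists with a conservative summit in the gene or within 2000 bp (points), with the mean and central 95% of 10000 length-matched random lists (ticks and grey bars). Ribosomal protein genes (74 of 88) and tracheal genes (22 of 23) lie above, as do EGF and FGF genes (14 of 15), which did not pass after adjustment, and chemosensory receptor genes (23 of 179) below.

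Of 13945 protein-coding genes, 6556 (47.0%) had a summit and 60 had 10 or more. The most summits were at kirre, a cell adhesion gene used in muscle fusion, with 34 over 394 kb. sbb had 27, CG1677 24, shn 20, hth and RapGAP1 19 each, pum 18, and cv-c, pyd and fz2 17 each. Per 10 kb of gene window sbb had 3.25 summits and shn 3.21, against 0.854 at kirre.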

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

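The alternative that leaves out genes near the peaks below was chosen after they were seen. In the ranked list that matches the conservative list, 184 peaks had an IDR at or under the threshold but are not among the 8309 peaks analysed here. They drew attention as signal outside the main measurement, above the limit that a count of 0 allows. They make up 2.17% of the 8493 passing peaks, and 115 of them lay on 3R. Of the 13945 protein-coding genes, 169 had such a peak of the conservative or the broader ranked list in their window. Leaving those genes out gave 3 called gene lists, as many as before. Few of the genes left out were in the called lists. They were 0 of 23 tracheal, 0 of 179 chemosensory receptor and 1 of 88 ribosomal protein genes. This setting could hardly change those calls, so the unchanged count does not show that they are robust. No explanation for these peaks was tested.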

How the results depend on the processing

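All alternatives here were planned, except the one without genes near the peaks not analysed, chosen after they were seen. Promoter share and octamer odds ratio kept their direction and side of the threshold under every alternative run. The promoter share went from 42.4% in the broader list, against 13.6% of random positions, to 55.5% within 1000 bp of a TSS, against 23.65%. That wider setting had the lowest ratio to random positions, 2.35. The octamer odds ratio went from 1.63 to 2.72. The replicate overlap of 72.4% was 66.05% for summits within 100 bp, 59.4% for a reciprocal overlap of 50% and 67.35% for equal numbers of top peaks. With either replicate left out, the density of X against the autosomes ranged from 0.814 to 0.978, and the octamer difference between strong and weak peaks from -1.47 to 2.21 points. Within the 4154 highest-signal peaks that difference was -2.70 points. The count of 6-mers was 298, against 496 in the 4154 highest-signal peaks and 176 with matched random windows. Called gene lists were 3, against 7 with random lists not matched on length, a setting in which 12% of unchanged lists of long genes had a permutation p under 0.05 in simulated data. Leaving out each replicate gave 2 to 4. Ribosomal protein and chemosensory receptor genes were called under all 8 alternatives, and tracheal genes under 3 of 8. Those 3 include the unmatched lists and the setting without genes near the peaks not analysed, which left out no tracheal gene. The count at vvl was 9, and 1 within 2 kb, as the narrower window implies. Except for the vvl window and the unmatched lists, the cause was not tested. Sequencing depth is not known, so its part in the difference between the replicates' lists stays open.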

Other observations

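The tests of words by location, of tRNA genes counted by cluster, of the octamer at promoters and of strong against weak peaks at promoters were chosen after results had been seen; the tRNA comparison per gene, the coding exon comparison and the strong against weak comparison away from TSSs were set out before theirs.

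Words at promoter peaks and at other peaks were compared with matched random windows, which had no peak of the broader list nearby. The matched promoter windows are therefore promoters without a nearby peak, not promoters in general. Against matched random windows, ATGCTAAT was found at 3.85% of the 4496 summits outside promoters and in 0.867% of windows, an odds ratio of 4.57 (Fisher's exact test, adjusted p = 7.97e-21), and the octamer at 8.99% against 3.91% (2.42; exact test, adjusted p = 6.92e-22). At the 3813 promoter summits the corresponding ratios were 0.919 (exact test, adjusted p = 0.910) and 1.58 (exact test, adjusted p = 0.00165). DRE had 7.05 at promoters (exact test, adjusted p = 9.56e-47) and 1.05 elsewhere (exact test, adjusted p = 1). The E-box CAGCTG had 1.89 at promoters (exact test, adjusted p = 2.17e-16) and 1.03 outside them (exact test, adjusted p = 0.910). The Twist E-box CATATG had 1.71 outside promoters (exact test, adjusted p = 6.80e-10) and 0.985 at them, where it did not pass. GAGAGAG was raised in both, at 2.92 and 3.195. The TATA word TATAAAAG was lower at promoter summits than in matched promoter windows, at 0.6075 (exact test, adjusted p = 0.00648), and had 1.14 elsewhere (exact test, adjusted p = 0.581). The differences between the locations were not themselves tested.

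Peaks gathered at promoters, those of ribosomal protein genes included. The octamer lay near 3.96% of promoter summits, 1.42 percentage points (0.621 to 2.21) above matched promoter windows, so it does not account for most of them. Background at strongly transcribed genes, which would raise tRNA genes too, is a candidate explanation. A summit lay within 500 bp of the start of 20% of 290 tRNA genes, against 26.2% of protein-coding genes (Fisher's exact test, p = 0.0179). This met the bound set beforehand against the explanation. Peaks gathered at protein-coding starts themselves, however, so a lower share than theirs cannot show that tRNA genes were not raised. A rise of tRNA genes over other positions was not tested. The bound also treated neighbouring tRNA genes, which share summits, as independent. With them counted once the value was 20.1% of 174 clusters (exact test, p = 0.0819). The background therefore stays open, no control sample was used here, and no biological explanation was tested.

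Summits were rare in coding exons, at 0.313%. GC content was weighed as a cause: points matched to the summits in arm, GC content and promoter status fell in coding exons in 5.14% of cases (4.69 to 5.73 over 100 draws). Matching lowered the share from 13.0%, but not through GC content alone. Matching in promoter status lowers it too, because promoters come before coding exons in the order of classes. The part of each in this fall was not separated. The share stayed above that of the summits in every draw, which argues against GC content, even with promoter status, as the whole cause. Other causes, such as chromatin accessibility, were not tested, and no biological explanation was tested.

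In the conservative list the difference in octamer share between strong and weak peaks did not pass its test, while the difference was 2.21 points in the list of replicate 1 and -2.70 points within the 4154 highest-signal peaks (exact test, p = 0.00748 and 0.0171). Strong promoter peaks without the octamer could hide a rise among the other peaks. Away from TSSs the difference was 0.623 points (-1.59 to 2.84; Fisher's exact test, p = 0.637), an interval that allows a rise or a fall, so this stays open. At promoters of the conservative list it was 1.89 points (0.2255 to 3.55; exact test, p = 0.0351, not adjusted). No biological explanation was tested.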
